A study of Nicotiana tabacum with 9 samples.

How the data were processed

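RNA from young leaves of *Nicotiana tabacum* was sequenced in 9 libraries, 3 for each of the genotypes NC82, M21 and G27. Per the labels, the libraries were made from total RNA as paired-end libraries and the leaves were taken at the squaring period, when flower buds form. The submitters' processing notes name HISAT2, StringTie and RSEM. Their versions, roles and settings, the genome build, the annotation and the strand setting are not given in the sources used here. The deposited table held 1 normalized expression signal per gene and library, made by the authors, for 69500 genes. Its header named no unit. The library sums lay between 771390 and 790816, so the values were scaled for depth, but whether they are TPM or FPKM could not be settled from the values. All levels below are in this unit. The table also held 3 columns of group means, which equalled the means of the library columns to within 3.3e-07 and were not used. Descriptions were protein domain names, and the table gave a gene name for 0 genes, so genes are named by identifier and domain.

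Libraries were assigned to groups by their labels. NC82, which is the name of a flue-cured tobacco cultivar, was taken as the reference. The labels do not say which line carries which change of NtAN3, nor whether replicates were separate plants, so p-values measure the spread between samples.

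The table held no counts. Each gene with a value of at least 1 in at least 3 libraries was tested, which gave 33188 genes. The log2 of the value plus a pseudocount of 1 was fitted for all 9 libraries together with limma 3.58.1 (empirical Bayes with a mean trend) in R 4.3.3. The 3 comparisons were M21 against NC82, G27 against NC82 and M21 against G27. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Calls use this pseudocount, so log2 changes of genes at low levels are smaller than the ratio of their means. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

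Read counts per library were not given. In a table of this kind, a gene with few reads takes values in steps of what 1 read is worth, so low genes shared by pairs of libraries give relative depths. Relative to NC82 replicate 1, set at 1, the other NC82 libraries lay at 1.21 and 0.96, the M21 libraries at 0.91, 0.81 and 0.87, and the G27 libraries at 1.0, 0.87 and 0.93. The deepest was 1.48 times the shallowest. Over the same 536 genes that gave these estimates, 62.1% of the ratios fell on 1 to 3 reads, against 24.5% for evenly spread ratios. This describes the fit and is not a separate check of the depths. No counting intervals can be given without counts.

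The method was tested on simulated data with known changes. Only 66 or 67 of 33188 genes were changed at each size, with noise that was independent between genes. A log2 change of 1 was recovered for 95.5% to 97% of genes, and a change of 0.585 for 59.7% to 80.6%, with 11 or 12 false calls per comparison. Far more genes were called in the data, so neither these shares nor this number of false calls carries over to them.

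Before the data were examined, 40 gene lists were fixed as word patterns on descriptions, of which 37 had 5 or more tested genes. The patterns for AN3 relatives, growth-regulating factors and D-type cyclins matched no description. Others took different genes than meant. The circadian pattern took mostly auxin and cation efflux carriers, the ethylene pattern mostly eRF1 release factors and folate enzymes, the stomata pattern stomatin-family proteins, and the KNOX pattern proteins with a CYSTM domain. The lignin pattern took laccases, the brassinosteroid pattern BZR1-type factors, the abscisic acid pattern mostly HVA22-related proteins, the chromatin remodelling pattern SNF2-related helicases, and the alkaloid pattern genes of quinolinate and ornithine metabolism. The defence, leaf size and pollen lists were mixed. The defence pattern also took TPR-repeat proteins and subtilase prodomains. After the descriptions had been seen, 42 lists were added, of which 41 had 5 or more tested genes. A few values of SS18 family genes and growth-regulating factors had been glimpsed by then. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the fixed and over the added lists separately, with an estimated correlation and with fry beside it.

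Named genes followed a rule set before the data were examined. It took every tested gene of the AN3 family, then the called gene of each fixed list that rose and the one that fell with the smallest p (24 at most per comparison, ranges apart), then the 5 with the largest rise and the 5 with the largest fall. Because the AN3 pattern matched none, the SS18 family, which holds AN3, took its place. Genes named outside the rule are marked as chosen after their values were seen.

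Overlap between the 2 lines was set against independent lists and against 20 simulated sets of unchanged lines sharing the NC82 libraries. It was also recomputed with separate NC82 libraries for each line, 1 for one line and 2 for the other, in all 6 ways. Alternatives were other scalings, pseudocounts, filters, thresholds, samples, a replicate block, and leaving out each library. Comparisons were also made over other splits of the libraries.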

Results

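Gene expression was measured in young leaves of 3 tobacco genotypes, NC82, M21 and G27, with 3 libraries each, in a study of how NtAN3 regulates leaf size. AN3 is a transcriptional co-activator of the SS18 family that promotes cell proliferation in leaves. Between 42762 and 44059 genes had a value above 0 in each library, and the 100 highest genes held 25.0% to 27.83% of a library's summed value. M21 libraries had estimated relative depths of 0.81 to 0.91, against 0.96 to 1.21 for NC82 and 0.87 to 1.0 for G27. The first principal component (43.9% of the variance) separated NC82 from both lines, and the second (20.8%) separated M21 from G27. On the third (11.6%), NC82 replicate 1, M21 replicate 3 and G27 replicate 1 stood apart from the other libraries of their groups. Values below are normalized expression as mean ± SD (n = 3), changes are log2 fold changes, and adjusted p are from limma.

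The SS18 family was asked first, because it holds AN3. Nitab4.5_0007901g0050 stood at 0.28 ± 0.052 in NC82, 5.04 ± 0.741 in M21 and 661.8 ± 85.5 (SD, n = 3) in G27. It rose by 9.01 (SE 0.11) in G27 against NC82, with a limma adjusted p of 7.4e-12, and by 2.23 in M21, with an adjusted p of 7.1e-07. M21 was lower than G27 by a log2 change of -6.78 (limma adjusted p = 1.6e-10). Nitab4.5_0001993g0030 fell in M21, from 8.38 ± 0.737 in NC82 to 6.62 ± 0.223, with a log2 change of -0.30 (limma adjusted p = 0.019). It was 8.75 ± 0.364 in G27, and M21 was lower than G27 by -0.36 (limma adjusted p = 0.016). The first of these calls was lost without NC82 replicate 1 or 3 or M21 replicate 1 or 3 (limma adjusted p = 0.057 to 0.075). The other was lost without M21 replicate 1 or 3 or G27 replicate 3 (limma adjusted p = 0.055 to 0.056). Nitab4.5_0000319g0250 (23.8, 23.0 and 25.1 in NC82, M21 and G27) and Nitab4.5_0000768g0010 (1.67, 1.38 and 1.36) were not called in any comparison. The other 2 family members were too low to be tested. Members share sequence, so how reads were divided among them is not known.

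**Figure D1:**
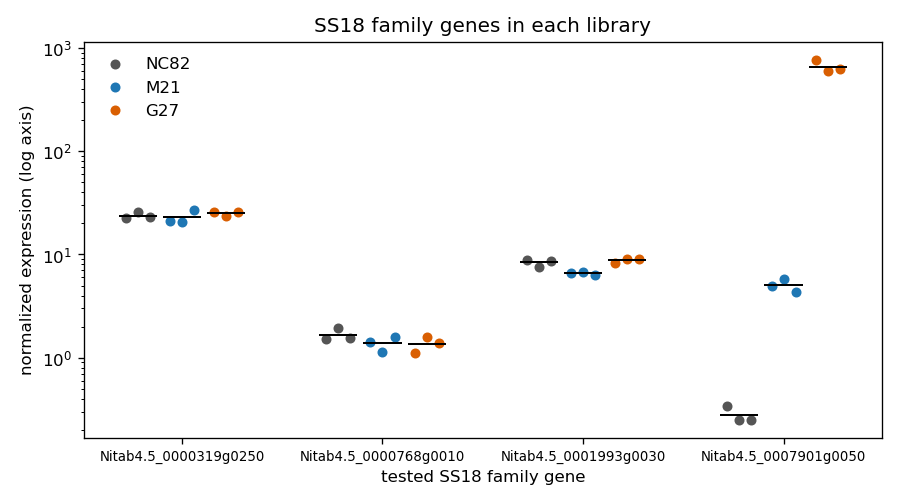
Normalized expression (log axis) of the 4 tested SS18 family genes in each library of NC82, M21 and G27, with bars at group means. Nitab4.5_0007901g0050 reached a mean of 661.8 in G27 and 5.04 in M21, against 0.28 in NC82.

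M21 against NC82 asked how this line departs from the cultivar. More WRKY, NB-ARC and chitinase genes rose than fell, and more expansins, laccases, aquaporins and ribosomal proteins fell than rose. A CAP-domain protein of the family that holds pathogenesis-related protein 1, Nitab4.5_0003771g0010, rose from 89.9 ± 12 to 1026 ± 111, and a relative, Nitab4.5_0004861g0030, rose from 22.3 ± 6.58 to 242.9 ± 28. The MADS-box factor Nitab4.5_0001339g0170 rose from 0.113 ± 0.0404 to 11.7 ± 0.707, and a protein phosphatase 2C, Nitab4.5_0000072g0070, from 0.183 ± 0.0709 to 11.9 ± 1.29. Of 274 ribosomal proteins of the eukaryotic type, 132 fell and 2 rose.

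The added lists gave most of the rises. Of 88 WRKY transcription factors, many of which act in defence, 57 rose and 0 fell, with Nitab4.5_0000006g0300 rising from 1.86 ± 0.115 to 8.50 ± 0.445. Of 146 NB-ARC proteins, the main class of intracellular resistance proteins, 48 rose and 0 fell. Of 23 chitinases, which break down fungal walls, 13 rose and 0 fell. Of 139 AP2/ERF transcription factors, 49 rose and 10 fell. With an estimated correlation the adjusted p of these lists was 0.49, 0.87, 0.49 and 0.49, so none of the camera calls held. Fry, which asks another question, gave adjusted p of 0.00057, 0.026, 0.00057 and 0.00057. The fixed defence list, which holds the WRKY genes, had 111 of 300 genes up and 29 down (adjusted over the list alone, 123 and 35), and its adjusted p was 0.71 with an estimated correlation. Its thaumatin Nitab4.5_0007816g0020 fell from 17.8 ± 1.5 to 2.49 ± 0.39.

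Lists of cell wall and transport genes went different ways. Of 32 expansins, which loosen walls during growth, 16 fell and 2 rose (adjusted over the list alone, 20 and 2). Of 12 laccases, 9 fell and 0 rose (adjusted over the list alone, 10 and 0). Of 52 aquaporins, which carry water, 23 fell and 7 rose (adjusted over the list alone, 27 and 9). Aquaporin Nitab4.5_0005236g0020 fell from 24.4 ± 0.759 to 7.10 ± 0.312, while Nitab4.5_0007733g0020 rose from 12.7 ± 0.701 to 28.96 ± 0.542. Of 27 phenylpropanoid and flavonoid genes, 16 fell and 2 rose (adjusted over the list alone, 19 and 2). A gene with chalcone/stilbene synthase domains, Nitab4.5_0003185g0100, was among those that rose, from 1.14 ± 0.1 to 7.49 ± 0.641. Xyloglucan endotransglucosylase/hydrolases, which remodel walls, went both ways, with 8 up and 8 down of 28 (adjusted over the list alone, 9 and 9), and Nitab4.5_0000404g0110 rose from 11.8 ± 0.397 to 49.4 ± 1. Of 39 cellulose synthesis genes, 9 rose and 6 fell (adjusted over the list alone, 10 and 8), and of 85 pectin genes 13 rose and 18 fell (adjusted over the list alone, 15 and 22). Of 46 genes of nitrate and nitrogen assimilation, 16 rose and 5 fell (adjusted over the list alone, 16 and 6). Of 43 tubulins, 17 fell and 0 rose. With an estimated correlation the adjusted p was 0.7 for expansins, 0.71 for laccases, aquaporins and phenylpropanoid genes, and 0.68 for tubulins.

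The ribosomal protein genes of the eukaryotic type had a median log2 change of -0.28, and 21 of the 25 cytosolic ribosomal proteins of the fixed list fell and 0 rose (adjusted over the list alone, 23 and 0). Their adjusted p was 0.56 and 0.21 with an estimated correlation. Their summed share was 2.29%, 2.19% and 2.48% of the M21 libraries, against 3.17%, 2.76% and 2.79% of the NC82 libraries. A term for NC82 replicate 1, M21 replicate 3 and G27 replicate 1, which stood apart on the third component, was added to the limma fit. By this term, 67 of the 274 genes were called higher in those 3 libraries and 3 were called lower. Of 8 growth-regulating factors, the DNA-binding partners of AN3, 1 rose and 2 fell, where 24.3% of all tested genes were called. Of 83 DNA replication genes 3 rose and 2 fell (adjusted over the list alone, 1 and 1), and of 78 core and linker histones 13 rose and 3 fell, as they did adjusted over the list alone. Camera with the preset correlation called both lists up, with adjusted p of 0.035 and 0.023, and of 0.91 and 0.71 with an estimated correlation. The first call was lost without NC82 replicate 1 (adjusted p = 0.15) or M21 replicate 3 (0.094), and the other without M21 replicate 3 (0.072). Of 42 cyclins, 2 rose and 9 fell, and of 49 mitosis genes 3 rose and 2 fell (adjusted over the list alone, 1 and 1). Of 12 inhibitors of cyclin-dependent kinases, 1 rose and 3 fell, as they did adjusted over the list alone (adjusted p = 0.71 with an estimated correlation). Of 38 genes in the leaf size list, 4 rose and 4 fell, as they did adjusted over the list alone.

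Single genes of metabolism also changed. An enzyme of glycoside hydrolase family 13, the family of amylases, Nitab4.5_0003541g0040, rose from 1.71 ± 0.27 to 17.3 ± 1.1, and sucrose-phosphate synthase Nitab4.5_0000009g0480 fell from 56.7 ± 4.1 to 19.1 ± 2.37. The delta-1-pyrroline-5-carboxylate synthetase Nitab4.5_0000987g0050, an enzyme of proline synthesis, fell from 34.4 ± 3.68 to 14.4 ± 0.5. A chaperonin, Nitab4.5_0004126g0010, fell from 172.2 ± 21.4 to 48.0 ± 2.63, and a small heat shock protein, Nitab4.5_0005259g0040, rose from 103.5 ± 4.23 to 237.2 ± 11.6. Phosphatases of the PHOSPHO type, Nitab4.5_0009182g0010 and Nitab4.5_0000255g0110, fell from 97.4 ± 9.8 to 17.6 ± 1.78 and from 62.1 ± 11.6 to 11.2 ± 0.32. The FAR1-domain gene Nitab4.5_0007303g0080 was listed at 0 in all 3 NC82 libraries and at 4.01, 8.21 and 20.7 in M21.

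In all, limma called 8064 of 33188 genes in M21 against NC82 at an adjusted p under 0.05, of which 4326 rose and 3738 fell. The direction with most calls turned with median-ratio scaling (4041 up and 4329 down) and without the 3 libraries that stand apart (3226 up and 3293 down). Of these, 919 changed by a log2 fold change of 1 or more (630 up and 289 down). The ranges of the groups did not overlap for 40.3% of all tested genes, where chance gives 10%. Among the called genes, which were chosen on the same values, the share was 99.1%. Camera with the preset correlation called 14 of the 37 fixed lists and fry 16. None of the 14 held with an estimated correlation, and another split of the same 6 libraries gave 15 by camera.

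G27 against NC82 asked the same of the other line. More DNA replication, histone and WRKY genes rose than fell, and more cytokinin, phenylpropanoid and aquaporin genes fell than rose. Of 83 DNA replication genes, 27 rose and 1 fell (adjusted over the list alone, 39 and 1), and of 78 core and linker histones 26 rose and 3 fell (adjusted over the list alone, 37 and 3). With an estimated correlation their adjusted p was 0.66 and 0.54. The histone H2A gene Nitab4.5_0003782g0030 was among those that fell, from 126.5 ± 3 to 76.4 ± 3.45. Of 49 mitosis genes, 1 rose and 3 fell, as they did adjusted over the list alone, and of 8 growth-regulating factors 2 rose and 1 fell. Of 274 ribosomal proteins of the eukaryotic type, 14 rose and 4 fell, with a median log2 change of 0.12. Camera called this list up with an adjusted p of 0.0027, and of 0.9 with an estimated correlation. The call was lost without NC82 replicate 2 (adjusted p = 0.064) or G27 replicate 1 (0.068).

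Of 88 WRKY genes, 44 rose and 1 fell, and of 146 NB-ARC genes 36 rose and 1 fell, with adjusted p of 0.9 for both with an estimated correlation. In the fixed defence list 83 of 300 rose and 11 fell (adjusted over the list alone, 103 and 17), with an adjusted p of 0.8 with an estimated correlation. Its chitinase Nitab4.5_0002926g0010 rose from 10.9 ± 2.4 to 65.3 ± 8.54, and its thaumatin Nitab4.5_0007816g0020 fell from 17.8 ± 1.5 to 3.44 ± 1.03. A heat shock transcription factor, Nitab4.5_0000090g0270, rose from 2.70 ± 0.674 to 17.1 ± 2.94. The family 13 glycoside hydrolase Nitab4.5_0003541g0040 rose to 19.2 ± 0.666, and the chalcone/stilbene synthase domain gene Nitab4.5_0003185g0100 to 6.34 ± 1.32.

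Lists of hormone, wall and sugar genes also differed from one another. Of 18 cytokinin genes, 10 fell and 2 rose (adjusted over the list alone, 11 and 2), with an adjusted p of 0.45 with an estimated correlation. In an added list of 35 two-component response regulators, 1 rose and 2 fell, with a median log2 change of -0.03. The cytokinin dehydrogenase Nitab4.5_0005779g0060, which degrades cytokinin, fell from 6.55 ± 0.105 to 3.15 ± 0.12. Of 16 gibberellin genes, 3 rose and 0 fell, as they did adjusted over the list alone. Of 27 phenylpropanoid and flavonoid genes, 13 fell and 2 rose (adjusted over the list alone, 14 and 3), with an adjusted p of 0.66 with an estimated correlation. Of 32 expansins, 6 fell and 0 rose (adjusted over the list alone, 8 and 0), with an adjusted p of 0.66 with an estimated correlation, and Nitab4.5_0003845g0060 fell from 23.3 ± 1.31 to 12.1 ± 1.29. In other wall lists more genes rose than fell, with 16 up and 8 down of 85 pectin genes (adjusted over the list alone, 18 and 11) and 7 up and 2 down of 39 cellulose synthesis genes (adjusted over the list alone, 8 and 2). Of 28 xyloglucan enzymes, 5 rose and 4 fell (adjusted over the list alone, 6 and 6). Of 52 aquaporins, 14 fell and 2 rose (adjusted over the list alone, 19 and 4), and of 190 sugar and starch genes 39 fell and 18 rose (adjusted over the list alone, 47 and 26). Their adjusted p was 0.8 and 0.84 with an estimated correlation. Sucrose-phosphate synthase Nitab4.5_0000009g0480 fell to 16.7 ± 1.79. PHOSPHO-type phosphatases Nitab4.5_0009182g0010 and Nitab4.5_0000255g0110 fell to 11.6 ± 0.781 and 9.35 ± 2.47, and the SPX-domain gene Nitab4.5_0000859g0200 from 20.9 ± 2.5 to 3.64 ± 0.602. SPX domains bind inositol phosphates and act in phosphate sensing.

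Some of the largest rises in G27 were led by G27 replicate 2. The 2-oxoglutarate-dependent dioxygenase Nitab4.5_0002015g0090 stood at 0.267 ± 0.127 in NC82 and at 8.61, 21.3 and 9.12 in the 3 G27 libraries. A glutathione S-transferase, Nitab4.5_0000641g0050, stood at 0.85 ± 0.432 in NC82 and at 17.5, 38.8 and 18.6. The MADS-box gene Nitab4.5_0000154g0260 was at 4.11 ± 0.92 in NC82 and listed at 0 in all 3 G27 libraries. It was at 0, 0 and 0.08 in M21.

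limma called 4620 genes in G27 against NC82, of which 2612 rose and 2008 fell, and 735 of them changed by a log2 fold change of 1 or more (504 up and 231 down). With median-ratio scaling 2312 rose and 2545 fell, so the direction with most calls turned. Ranges did not overlap for 30.6% of all tested genes, where chance gives 10%, and for 99.6% of the called genes, which were chosen on the same values. Camera with the preset correlation called 14 of the 37 fixed lists and fry 7. None of the 14 held with an estimated correlation, and another split of the libraries gave 13.

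M21 against G27 tested the difference between the 2 lines. The NC82 libraries do not enter the fold changes, but they enter the spread behind the p-values. More ribosomal protein genes were lower in M21 than higher, and more cytochrome P450, AP2/ERF and B-box genes were higher than lower. Of 274 ribosomal proteins of the eukaryotic type, 188 were lower in M21 and 1 was higher, with a median log2 change of -0.42 (adjusted p = 0.3 with an estimated correlation). In the fixed list of cytosolic ribosomal proteins, 22 of 25 were lower and 0 higher (adjusted over the list alone, 24 and 0), with an adjusted p of 0.075 with an estimated correlation. Nitab4.5_0005219g0100, protein L18a of the large subunit, stood at 50.1 ± 2.52 in M21 and 83.4 ± 6.39 in G27.

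Of 188 cytochrome P450 genes, 53 were higher in M21 and 2 lower (adjusted p = 0.32 with an estimated correlation). Of 139 AP2/ERF factors, 28 were higher and 4 lower (adjusted p = 0.32 with an estimated correlation). Of 60 B-box and CCT domain proteins, the class of CONSTANS-like regulators, 11 were higher and 0 lower (adjusted p = 0.35 with an estimated correlation). Of 30 terpene synthases, 8 were higher and 0 lower (adjusted p = 0.35 with an estimated correlation). Of 34 members of the heat shock protein 70 family, 12 were lower and 0 higher (adjusted p = 0.57 with an estimated correlation). Aux/IAA proteins, repressors of auxin response, had 10 of 40 lower and 1 higher (adjusted p = 0.59 with an estimated correlation). One of them, Nitab4.5_0002438g0090, stood at 2.43 ± 0.72 in M21 and 8.91 ± 1.54 in G27, with 4.5 ± 0.834 in NC82.

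Of 52 aquaporins, 15 were lower in M21 and 5 higher (adjusted over the list alone, 17 and 7), with an adjusted p of 0.71 with an estimated correlation. Of 190 sugar and starch genes, 33 were higher and 8 lower (adjusted over the list alone, 41 and 11), with an adjusted p of 0.72 with an estimated correlation, and the SWEET sugar transporter Nitab4.5_0009485g0020 stood at 101.5 ± 0.622 in M21 and 59.98 ± 5.12 in G27. Of 83 DNA replication genes, 9 were lower and 0 higher (adjusted over the list alone, 8 and 0), with an adjusted p of 0.72 with an estimated correlation. The MADS-box factor Nitab4.5_0001339g0170 was at 11.7 ± 0.707 in M21 and 0.0833 ± 0.0764 in G27. A fatty acyl-CoA reductase, Nitab4.5_0002609g0030, of the class that makes wax alcohols, was at 7.30 ± 1.72 and 1.36 ± 0.434. A gibberellin-regulated protein, Nitab4.5_0000201g0290, was at 7.36 ± 0.426 and 21.3 ± 4.63. Genes of the Dicer type, which make small RNAs, were lower in M21 at 2 loci, with Nitab4.5_0001003g0020 at 3.01 ± 0.156 and at 23.7, 53.3 and 22.7 in the G27 libraries, and Nitab4.5_0019786g0010 at 6.59 ± 1.05 and at 31.7, 59.1 and 28.0.

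limma called 3941 genes in M21 against G27, of which 1817 were higher in M21 and 2124 lower, and 250 differed by a log2 fold change of 1 or more (109 higher and 141 lower). The direction with most calls turned with median-ratio scaling (2111 higher and 1929 lower), without M21 replicate 2 (1477 and 1468) and without G27 replicate 1 (1526 and 1493). Without M21 replicate 1 the count was 2283. Ranges did not overlap for 28.6% of all tested genes, where chance gives 10%, and for 99.8% of the called genes, which were chosen on the same values. Camera with the preset correlation called 12 of the 37 fixed lists, fry called 5, and 0 of the 12 held with an estimated correlation. Without M21 replicate 2, camera called 8.

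**Figure D2:**
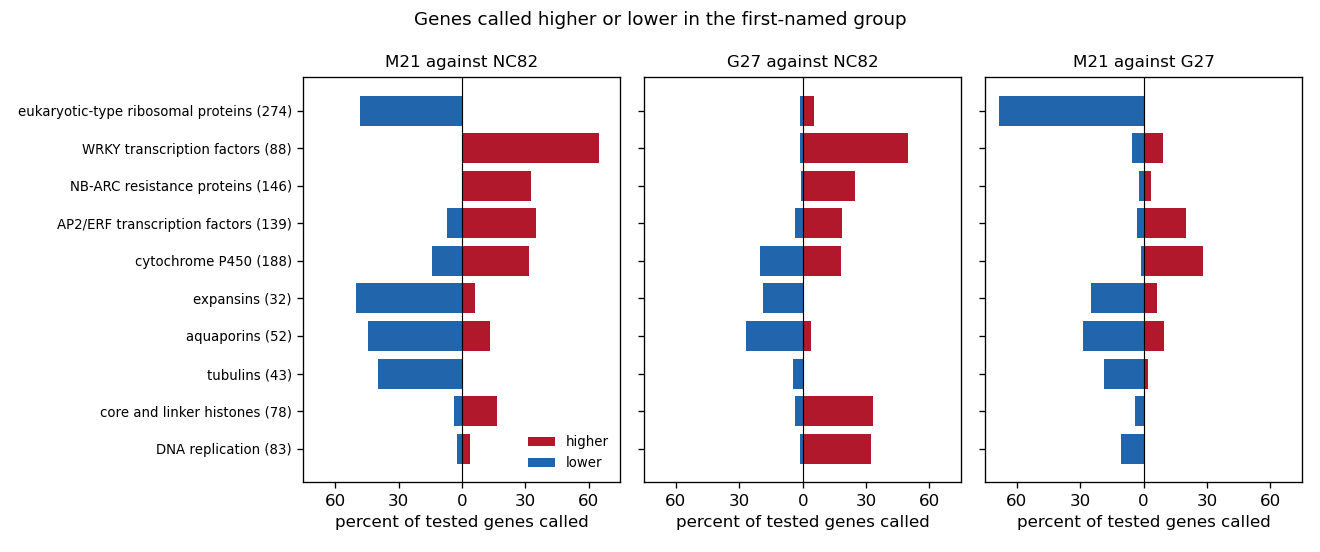
Percent of tested genes called higher (right) or lower (left) in the first-named group, for 10 gene lists chosen after the results were seen, with the number of tested genes in brackets. Of 274 ribosomal proteins of the eukaryotic type, 132 were called lower in M21 against NC82 and 188 against G27 (adjusted p = 0.56 and 0.3 for the list with an estimated correlation).

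**Figure D3:**
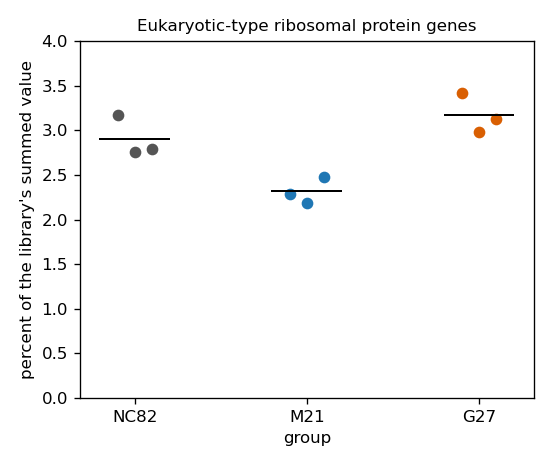
Share of each library's summed value held by the 274 ribosomal protein genes of the eukaryotic type, in percent, with bars at group means. The 3 M21 libraries lie at 2.19% to 2.48%, and the lowest of the others lies at 2.76%.

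The patterns that took other genes than meant gave these counts. The circadian list, mostly efflux carriers, had 11 of 62 genes up and 13 down in M21 against NC82 (adjusted over the list alone, 11 and 15), and 6 up and 12 down in G27 (adjusted over the list alone, 7 and 15). The ethylene list, mostly release factors and folate enzymes, had 0 of 28 up and 4 down in M21, as it did adjusted over the list alone, and 1 up and 1 down in G27 (adjusted over the list alone, 0 and 1). Of 16 stomatin-family proteins, 6 rose and 1 fell in M21, as they did adjusted over the list alone, and 4 rose and 0 fell in G27 (adjusted over the list alone, 4 and 1). Of 6 CYSTM proteins, 2 rose and 1 fell in M21 (adjusted over the list alone, 3 and 1), and 0 rose and 1 fell in G27, as they did adjusted over the list alone. Of 15 BZR1-type factors, 1 rose and 3 fell in M21 and 0 rose and 1 fell in G27, as they did adjusted over the list alone. Of 26 genes in the abscisic acid list, mostly HVA22-related, 4 rose and 1 fell in M21, as they did adjusted over the list alone, and 5 rose and 2 fell in G27 (adjusted over the list alone, 8 and 2). Of 62 SNF2-related helicases, which include the ATPases of the complexes AN3 recruits, 2 rose and 2 fell in M21 (adjusted over the list alone, 1 and 2), and 3 rose and 2 fell in G27 (adjusted over the list alone, 2 and 2). Of 9 genes in the alkaloid list, 2 rose and 2 fell in M21, as they did adjusted over the list alone, and 2 rose and 2 fell in G27 (adjusted over the list alone, 3 and 3). Laccases had 0 of 12 called in G27, also adjusted over the list alone. The leaf size list had 2 of 38 up and 1 down in G27 (adjusted over the list alone, 1 and 0). The pollen list, made of expansins and Ole e 1 proteins, had 11 of 74 up and 23 down in M21 (adjusted over the list alone, 11 and 27), and 3 up and 10 down in G27 (adjusted over the list alone, 6 and 14).

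The overlap asked how far the 2 lines departed from NC82 together. In both lines 1857 genes rose, where independent lists give 340, and 1335 fell, where they give 226. WRKY factor Nitab4.5_0000006g0300 stood at 1.86 in NC82, 8.50 in M21 and 5.10 in G27, and nitrite/sulfite reductase Nitab4.5_0004741g0010, of a family that assimilates nitrogen or sulfur, at 47.7, 26.8 and 26.0. The xyloglucan enzyme Nitab4.5_0002630g0010 stood at 20.1, 96.4 and 60.1. The CBS-domain gene Nitab4.5_0002752g0140 stood at 6.43, 0.533 and 0.0667. In opposite directions, 44 genes rose in M21 and fell in G27, and 25 fell in M21 and rose in G27, where independent lists give 262 and 294. Because both comparisons use the same NC82 libraries, some sharing arises without any change in the lines. Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of 0.71, against 0.5 in simulated unchanged lines, and a covariance of 0.096, against 0.009. When each line had NC82 libraries of its own, 1 for one line and 2 for the other, the covariance was 0.083 to 0.088 and the correlation 0.54 to 0.62 over the 6 divisions. In these divisions 1405 to 1994 genes were called in the same direction, where independent lists give at most 284. Of the 3192 genes called in the same direction, 454 were also called in M21 against G27.

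**Figure D4:**
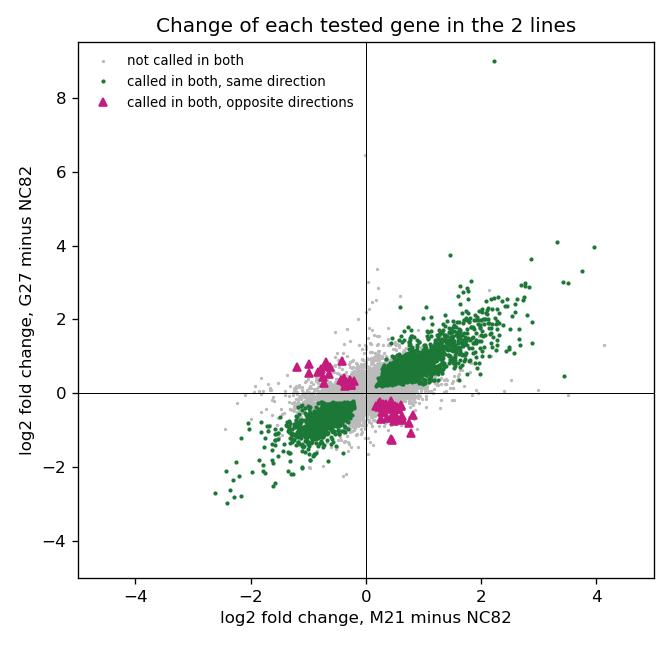
Log2 fold change of each tested gene in M21 (horizontal) and G27 (vertical) against NC82, with genes called in both lines in the same direction (3192) and in opposite directions (69) marked. Axes share the NC82 libraries.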

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

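The tests of carry-over, family reads, shared controls, genetic background and scaling were chosen after the results they weigh had been seen, as was the grouping of NC82 replicate 1, M21 replicate 3 and G27 replicate 1.

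The lines differed in the SS18 family gene Nitab4.5_0007901g0050, by -6.78 in M21 against G27 on the log2 scale, in a direct test of the difference. Its M21 mean was 0.76% of its G27 mean (libraries 0.65% to 0.88%), against 0.042% in NC82. Carry-over of G27 reads into M21 could give such a level. A search found 0 other genes with a G27 mean of 20 or more and an NC82 mean of 0.5 or less, so it could not test carry-over. Genes high in G27 and low in M21, whatever their NC82 level, were not searched. Reads of the other 5 family members might also be counted here, since their sum changed by -2.84 (SE 2.1) where this gene gained 4.76. Their sum was 34.1 in NC82 and 31.3 in M21, while this gene stood at 0.28 in NC82. That argues against a share of those reads that is equal in NC82 and M21. A share that differs between them stays open, so neither carry-over nor family reads is settled. Either would raise the M21 level, so the rise over NC82 stays open, a real rise included, and the distance below G27 would be understated.

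The lines also differed in 69 genes called in opposite directions against NC82. All 69 were called in M21 against G27 as well. That change is the difference of the other 2 changes in the same fit, so opposite calls nearly ensure it. The third call is therefore not separate evidence. Among the 69 genes, picked after their values were seen, was a stress-responsive alpha-beta barrel protein, Nitab4.5_0011810g0030. It stood at 24.2 in NC82, 10.1 in M21 and 40.4 in G27. A gamma-tubulin complex gene, Nitab4.5_0000615g0100, stood at 1.97, 4.2 and 0.41, and a profilin, Nitab4.5_0002423g0020, at 1.39, 0.2 and 3.18.

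Far more genes (3192) changed in the same direction in both lines. With separate NC82 libraries for each line, the covariance of the changes was at least 0.083 in all 6 divisions, against 0.096 with shared libraries, which argues against chance values of the shared NC82 libraries as the whole source. Among 5776 genes with a mean of 20 or more, where depth matters little, 590 (10.2%) were called in both lines in the same direction. Of the other tested genes 9.5% were. For the 590 genes this argues against the greater depth of the NC82 libraries. Most of the 3192 genes had lower means, and for them an effect of depth was not tested. A genetic background shared by the lines and not by NC82 may contribute. Genes were counted that differed in 1 group from both others by a log2 change of 3 or more, ranges apart. With the pseudocount of 1, low genes can be 8-fold apart in value and fall short of this. The counts were 4 for NC82, 1 for M21 and 3 for G27. This missed the bound set for it (2 times either line). A rule for counting spread, added only after that result was seen, left the background undecided. The other tabulations gave 48, 7 and 12 (a log2 change of 2 or more) and 9, 0 and 1 (absent against present). Both pass that bound, though it was not set for them. Growth, harvest and library batches are not given in the labels, so they cannot be told apart from the groups, and an effect of NtAN3 common to both lines stays open as untested.

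Ribosomal protein genes of the eukaryotic type were lower in M21 than in G27, with a median of -0.42, in a direct test of the difference that was lost with an estimated correlation (adjusted p = 0.3). Against NC82 their median was -0.28 in M21 and 0.12 in G27. In G27, 14 of the 274 genes rose and 4 fell (adjusted over the list alone, 2 and 3). The camera call of the list in G27 was lost without NC82 replicate 2 or G27 replicate 1. Whether G27 adds to the difference between the lines is therefore not settled. The M21 median was -0.31 with median-ratio scaling, which argues against a shift of all genes. Of 10000 random lists matched on abundance, the lowest median was -0.081, which argues against depth or abundance. The 982 other genes that were higher in the 3 libraries standing apart had a median of 0.13 in M21 against NC82, the opposite direction, which argues against that axis. Transcript length and GC content were not tested for lack of transcript sequences, so a length or GC trend stays open beside a biological difference.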

How the results depend on the processing

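The alternatives chosen after the data were seen were leaving out the 3 libraries that stand apart, overlap with each line in its own fit, separate NC82 libraries for each line, and all alternatives for the added lists. No called list, and none of the named genes called, changed direction in its test under the alternatives run for it (directions of the other called genes were not compared), but the median of aquaporins in G27 against NC82 went from -0.07 to 0.01 without NC82 replicate 3, and that of SBP-box factors in M21 against NC82, an added list, from -0.06 to 0.03 without M21 replicate 2. Calls of genes in M21 against NC82, G27 against NC82 and M21 against G27 (8064, 4620 and 3941) were 8370, 4857 and 4040 with median-ratio scaling, 8129, 4693 and 3995 with a common total, 7963, 4559 and 3540 without a filter, 8037, 4609 and 3827 with a pseudocount of 0.1, and 8005, 4223 and 3331 with only the 6 libraries. Median-ratio scaling moved the share of calls that rose from 53.6% to 48.3%, from 56.5% to 47.6% and from 46.1% to 52.3%, so the direction that held most calls turned in all 3 comparisons. By construction, fewer passed with an absolute log2 change of 1 or more (919, 735 and 250, and 483 in both lines) and at an adjusted p under 0.01 (4755, 2706 and 1675). Leaving out 1 library gave 5874 to 7550, 3251 to 4152 and 2283 (without M21 replicate 1) to 3119 genes, 2319 to 3116 genes in both lines, and 11 to 15, 12 to 14 and 8 (without M21 replicate 2) to 13 lists. Without the 3 libraries that stand apart the counts were 6519, 3626 and 2851, and with each line in its own fit 2924 genes were shared. With NC82 replicate 1, 2 or 3 for M21 and the others for G27, 1994, 1684 and 1860 genes were called in both lines, and with it for G27 and the others for M21, 1794, 1405 and 1674. These divisions leave fewer libraries per comparison, and the lone library is assumed to vary like the others.

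Of the fixed lists, 14, 14 and 12 were called by camera with the preset correlation, 0, 0 and 0 with an estimated correlation, and 16, 7 and 5 by fry, which asks another question. The cause of the fall with an estimated correlation was not tested. Of the added lists, 14, 9 and 16 were called, 0, 0 and 0 with an estimated correlation, and 16, 5 and 14 by fry. With a library left out, 641 values of named genes kept their side of the threshold, and 7 did not, all of Nitab4.5_0001993g0030. The replicate block gave 7846, 4443 and 3720 genes, 3083 in both lines, and 14, 13 and 12 lists. Residual correlations of samples sharing a number ran from -0.21 to 0.34, and not every sample correlated best with its own number, so the numbers were not taken to pair samples.

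A planned count model was not run, since the table holds no counts, and the planned stricter filter and limma on log values are the analysis reported. Without read counts, precision at low values is not known.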

Other observations

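The gene groups in the first 2 paragraphs were picked after their values were seen, out of 6 groupings tried, and all 6 are given beside the growth-regulating factors of an added list. The splits of the libraries were planned.

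Among genes of phosphate use, more fell than rose in both lines in most groupings. Of 25 genes with an SPX domain, 10 fell and 3 rose in M21 against NC82, and 11 fell and 0 rose in G27. Nitab4.5_0008963g0030 stood at 12.6 ± 0.852 in NC82, 2.46 ± 0.456 in M21 and 2.1 ± 0.257 (SD, n = 3) in G27. Of 5 PHOSPHO-type phosphatases, 3 fell and 0 rose in each line, and Nitab4.5_0014046g0010 stood at 159 ± 30.6, 46 ± 3.87 and 34.9 ± 7.12. Of 31 purple acid phosphatases, 10 fell and 2 rose in M21, and 12 fell and 0 rose in G27. Of 7 glycerophosphodiester phosphodiesterases, 2 fell and 1 rose in M21, and 2 fell and 2 rose in G27, and Nitab4.5_0002172g0020 stood at 164 ± 1.39, 65.7 ± 3.99 and 70.8 ± 2.8. A combined group of 22 phosphate-response genes had 11 down and 2 up in each line, with an unadjusted camera p of 3.7e-06 and 1.4e-11, and of 0.088 and 0.025 with an estimated correlation. These p-values are not independent evidence, since the group was picked on the same data.

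Of 39 Dicer, Argonaute and RNA-dependent RNA polymerase genes, 7 rose and 0 fell in G27 against NC82, and 2 rose and 3 fell in M21. In M21 against G27, 7 were lower and 1 higher, with an unadjusted camera p of 0.28 with an estimated correlation. Among the growth-regulating factors, Nitab4.5_0005167g0090 stood at 0.48 ± 0.157 in NC82, 0.47 ± 0.335 in M21 and 2.17 ± 0.139 in G27, and rose in G27 by 1.1 on the log2 scale (limma adjusted p = 0.00074). Nitab4.5_0001033g0050 rose in M21, from 7.02 ± 0.599 to 10.3 ± 1.78 (limma adjusted p = 0.015). Nitab4.5_0001494g0010 fell in M21, from 7.97 ± 0.324 to 6.07 ± 0.135 (limma adjusted p = 0.0064). Nitab4.5_0001426g0010 fell in both lines, from 3.31 ± 0.0551 to 2.46 ± 0.215 in M21 and 2.36 ± 0.182 in G27 (limma adjusted p = 0.022 and 0.018). Nitab4.5_0004686g0010 rose in G27, from 0.903 ± 0.232 to 1.6 ± 0.227 (limma adjusted p = 0.033).

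Among genes absent in 1 group and present in the others, 8 were under 0.1 in every NC82 library and at 1 or more in every library of both lines. They include a C2-domain gene picked after its values were seen, Nitab4.5_0000494g0060, listed at 0 in NC82 and at a mean of 3.04 in M21 and 2.6 in G27. On the axis that sets NC82 replicate 1, M21 replicate 3 and G27 replicate 1 apart, a group of 3 samples defined from the data, 1446 genes were called. Of 71 chlorophyll a/b binding proteins, 44 were lower in those 3 libraries and 1 was higher, with a median of -0.21 (adjusted p = 0.44 with an estimated correlation).

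For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split gave 8064 genes in M21 against NC82 and the highest other 3, in G27 against NC82 4620 and 2, and in M21 against G27 3941 and 1, with 1 of the 10 splits as large in each. For the fixed lists, by camera with the preset correlation, the real split gave 14 and the highest other 15 in M21 against NC82, with 2 of the 10 as large. The real and the highest other gave 14 and 13 in G27 against NC82, and 12 and 9 in M21 against G27. Another split thus called more lists than the real one in M21 against NC82, and fewer in the other comparisons. For genes called in both lines, 1 of 100 splits drawn from 840, the real one included, gave as many as the real 3192. This is the lowest share that 100 splits can give. Splits with a mixed reference break up the real groups, so the share does not test whether the lines share changes by chance. The highest other, 2575, kept the 3 NC82 libraries as the reference, splits with the libraries of M21 or G27 as the reference reached 2540, and those with a mixed reference reached 2.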
